A study of Sus scrofa with 8 samples.

How the data were processed

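Bulk RNA sequencing of pig limb muscle gave 8 libraries, 2 for each of 4 groups: wild type and knockout of MYF5, MYOD1 and MYF6, each at embryonic days 41 and 62. Groups and replicate numbers come from the sample titles. The series title says knockdown where the samples say knockout, and the growth protocol gives day 60 for the later stage. Per the labels' protocols, libraries were made with a TruSeq RNA or a TruSeq Stranded mRNA kit, and strand is not stated for the counting, so a gene and its antisense partner cannot be told apart.

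The deposited table holds estimated counts per gene (expected counts), which are whole numbers and not normalized, with 1 column per library. The submitters' processing notes name kallisto and DESeq2, and the builds Sscrofa11.1 and susScr11, without a role or version; the annotation release, filters and rounding are not given in the sources used here. Estimated counts divide reads among near-identical copies, so ribosomal protein genes, the IFIT family and other close paralogs are uncertain. No genome was used here, so no coordinates are given. Symbols were found for 15527 of 22516 gene identifiers (69.0%), and the other genes entered the tests under their identifier alone.

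Totals ranged from 23402052 to 60539245 counts per library. Genes with 0 counts everywhere numbered 2564. After edgeR's filterByExpr with its default minimum count of 10, 17020 genes were tested, 14082 of them with a symbol, and these held at least 99.98% of the counts of every library. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom of 31.9, 45.9, 70.9 and 68.4), so each library counted as 1 sample. Library names carry the number 0991 in wild-type E41, 0923 in knockout E41, 0987 in wild-type E62 and 4281 in knockout E62.

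Counts were rounded, scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group over all 8 libraries, a robust quasi-likelihood fit and 4 residual degrees of freedom; the common biological coefficient of variation was 0.204. The quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjusted p under 0.05, was used for knockout against wild type at each stage, for the difference of these effects between stages, and for E62 against E41 within each genotype. Overlaps of calls were set against independent lists by Fisher's exact test. A group with 0 counts gives a fold change of at least the ratio to a floor of 3 counts over the group, and a group with 1 to 3 counts a ratio with its 95% Clopper-Pearson interval.

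Of 36 gene lists written before the data were examined, with 672 genes, 569 were tested, and 35 lists had the 3 measured genes needed; sex-linked genes did not. Lists cover the targeted genes, muscle progenitors, differentiation, sarcomere, coupling, neuromuscular junction, energy metabolism, dystrophin complex, cardiac-type muscle, tissues a dissected limb could hold, signalling pathways, proliferation, translation and respiration. Lists were tested by camera (limma 3.58.1) with a preset correlation of 0.01 and adjusted over lists. A camera test with the correlation estimated from the data and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were alternatives. List medians have genes with 3 counts or fewer in a group at their floor or ratio.

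Genes were named by a rule also written before the data were examined. It takes the 3 targeted genes and PAX3, PAX7 and MYOG. In each genotype comparison it takes the 8 largest rises and 8 largest falls among genes past the threshold, with a symbol, a mean of at least 2 CPM and no overlap between the groups. In each other comparison it takes 4 each way, with overlap allowed for the difference between stages. From each list it takes up to 4 measured genes with the smallest p and up to 2 called against the majority; which of these to name was decided after their values were seen. The alternatives were DESeq2 1.42.0, limma-voom, relative log expression factors, library size alone, TMM from genes outside the muscle lists, no low-count filter, at least 1 CPM of the unscaled total in 4 libraries, counts thinned to the smallest library, the replicate number as a block, only the groups compared, at least a 2-fold change, and each library left out in turn.

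The steps were tested on simulated data with genes changed at E41 only. Of 16691 simulated genes, 30 of 50 changed 2-fold were recovered, and 41, 48 and 47 of 50 at 4-fold, 8-fold and 16-fold, with 8 calls among unchanged genes. In the list test, run on 17020 simulated genes, the 1 shifted list was called and 0 of 35 unchanged lists. Simulated genes were independent and far fewer changed than in the data, so co-varying lists and wide change were not tested.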

Results

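Limb muscle from pig embryos was profiled by bulk RNA sequencing on embryonic days 41 (E41) and 62 (E62). Wild-type animals were compared with embryos carrying a knockout of MYF5, MYOD1 and MYF6, the transcription factors that set up the skeletal muscle lineage. In library names WT is wild type and KO knockout. Each of the 4 combinations of genotype and stage had 2 libraries. Total counts were 23402052 and 25239378 in wild-type E41, 42352383 and 42668408 in knockout E41, 35867841 and 37676855 in wild-type E62 and 60539245 and 52630708 in knockout E62. The design asks which genes and cell types of the limb muscle depend on the 3 factors, and whether that differs between the stages. Of 17020 genes tested, 6678 changed in the knockout at E41 and 8028 at E62.

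Genotype separated the libraries on the first principal component of the 500 most variable genes, which held 73.0% of their variance. The component after it held 19.7%. On it KO E62 replicate 2 (52.6) stood 41.2 from replicate 1 (11.4), against at most 8.28 between replicates of other groups, and this pair had the lowest correlation (Pearson's r of log CPM 0.967, against 0.972 to 0.987). Sample titles call the replicates biological, and library names within a group differ in a number (after Emb in knockout E62), but the animals are not stated, so p-values measure the spread between these libraries. In the library names each group carries a number of its own, and wild-type E41 names carry a limb code of their own. A litter or preparation batch therefore cannot be told apart from the group, nor the limb where wild-type E41 is compared. Values with ± are log2 fold changes with a standard error, n = 2 libraries per group, unless stated as SD. This standard error is the change over the square root of its F statistic, and can be too small where a group has few counts. Medians of lists are of log2 changes. Adjusted p of genes come from edgeR and those of gene lists from camera, both by the Benjamini-Hochberg method. Ranges in brackets after camera p are over alternatives, and leave out the estimated correlation given beside them. List-adjusted counts come from p adjusted over the list alone. Intervals and floors of counts cover counting error only.

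MYF5 (ENSSSCG00000000937) and MYF6 (ENSSSCG00000026533) had 0 counts in all 4 knockout libraries. In wild type, MYF5 stood at 49.8 ± 5.69 CPM (counts relative to the TMM-scaled library total; mean ± SD, n = 2) at E41 and 79.4 ± 24.3 at E62, and MYF6 at 27.7 ± 2.92 and 106 ± 3.46. With a floor of 3 counts over the group, MYF5 was at least 1542-fold lower at E41 and at least 3374-fold lower at E62. MYF6 was at least 856-fold lower at E41 and at least 4504-fold lower at E62. MYOD1 (ENSSSCG00000013375) kept 28 and 20 counts in the knockout E41 libraries and 77 and 88 in the knockout E62 libraries, against 1503 and 2161 and 5715 and 5203 in wild type. Its log2 change was -7.33 ± 0.24 at E41 (edgeR adjusted p = 9.9e-07) and -6.96 ± 0.22 at E62 (adjusted p = 5.2e-07). All 3 genes of the targeted list were lower at both stages (0 and 3 list-adjusted, camera adjusted p = 6.9e-24 at E41 and 9.4e-20 at E62).

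MYOG, the factor that drives terminal muscle differentiation, fell to 2 and 2 counts at E41 (log2 change -12.99 ± 0.27). At E62 it had 1 and 0 counts and was 77574-fold lower (interval 13922 to 3064075) than in wild type. PAX7, the marker of muscle stem cells, kept 84 and 18 counts in the knockout at E41 against 1738 and 1854 in wild type, a log2 change of -6.23 ± 0.61 (adjusted p = 0.0011). At E62 it had 0 and 1 counts against 3871 and 2869 and was 12808-fold lower (interval 2298 to 505949.8). PAX3, which marks the migrating progenitors of limb muscle, had 96 and 81 counts against 7 and 32 at E41 and 75 and 19 against 11 and 2 at E62. Neither difference passed the edgeR test (adjusted p = 0.35 and 0.15).

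**Figure D1:**
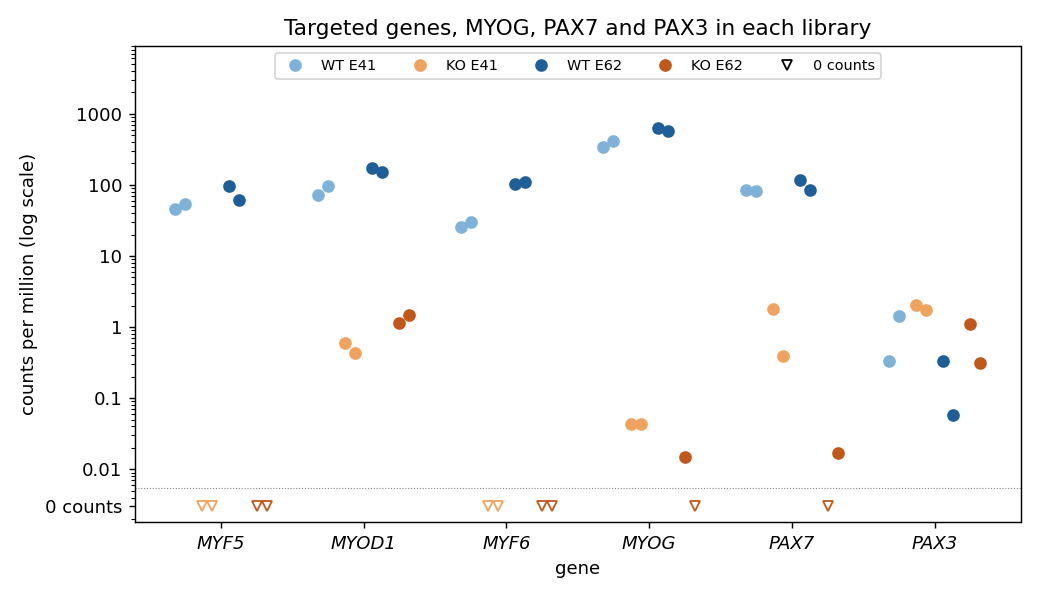
CPM (log scale) of the 3 targeted genes, MYOG, PAX7 and PAX3 in each of the 8 libraries, 1 point per library, with open triangles for libraries at 0 counts. MYF5 and MYF6 sit at 0 counts in all 4 knockout libraries, while MYOD1 keeps 28, 20, 77 and 88 counts there.

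At E41 the transcripts of differentiated muscle were far lower in the knockout. Of 37 sarcomere genes, 0 were higher and 35 lower (0 and 36 list-adjusted), with a median of -8.64. Light chains of muscle myosin were among the largest falls by rule: MYL11 (-14.71 ± 0.26), MYL1 (-13.82 ± 0.25) and MYL2 (-13.68 ± 0.26). MYL4, the embryonic light chain, was 33126-fold lower (interval 11334 to 160635). MYOZ2, which tethers calcineurin at the Z-disc, was 28112-fold lower (interval 7782 to 232145), and the small muscle protein gene SMPX 17538-fold lower (interval 3147 to 692779). Of 17 differentiation and fusion genes, 0 were higher and 15 lower (0 and 15 list-adjusted), with a median of -6.64. They included SMYD1, a methyltransferase of myofibril assembly (-10.11 ± 0.18), the cadherin CDH15 (-7.41 ± 0.16) and KLHL40 (-6.38 ± 0.13). Of 20 excitation-contraction coupling genes, 0 were higher and 17 lower (0 and 19 list-adjusted), with a median of -5.82. The calcium pump ATP2A1 (-9.67 ± 0.26), its regulator SLN (-9.65 ± 0.19) and the release channel RYR1 (-8.29 ± 0.24) were among those that fell.

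At the neuromuscular junction, 9 of 13 genes were lower and 1 higher (1 and 9 list-adjusted), with a median of -2.51. CHRNG, the fetal subunit of the acetylcholine receptor, had 0 counts and was at least 3473-fold lower. The subunit CHRND was 4605-fold lower (interval 826 to 181989.8). The receptor kinase MUSK changed by -9.63 ± 0.19, while AGRN, its activator from nerve terminals, rose by 1.33 ± 0.19. Of 20 energy metabolism genes, 1 was higher and 17 lower (1 and 17 list-adjusted), with a median of -1.84. Creatine kinase CKM changed by -8.39 ± 0.21 and the enolase ENO3 by -4.0 ± 0.22, and PDK4, which restrains glucose oxidation, rose by 0.91 ± 0.23. For PDK4, the adjusted p of 0.016 became 0.080 without WT E41 replicate 1 and 0.084 without KO E41 replicate 2 (0.0018 to 0.084 over alternatives). Of 11 dystrophin complex genes, 2 were higher and 9 lower (2 and 9 list-adjusted), with a median of -1.31. SGCA changed by -5.45 ± 0.18 and DMD, dystrophin itself, by -2.24 ± 0.16. Muscle genes shared with the heart had 7 of 9 lower and 1 higher (1 and 7 list-adjusted), with a median of -3.44. Their median was -11.93 with the 1 CPM filter. The actin ACTC1 changed by -13.46 ± 0.36 and the limb and heart factor HAND2 by 1.92 ± 0.31.

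Of 15 muscle progenitor regulators, 1 was higher and 9 lower (1 and 11 list-adjusted), with a median of -2.80. The muscle factors PITX3 (-6.34 ± 0.30) and LBX1 (-3.71 ± 0.37) fell and DMRT2 (0.83 ± 0.17) rose. Camera adjusted p of these muscle lists at E41 ranged from 1.2e-177 for the sarcomere to 0.00017 for the progenitor regulators. With an estimated correlation they ranged from adjusted p = 0.0013 for differentiation to 0.0495 for the progenitor regulators, and each list stayed past the threshold in every other alternative.

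Proliferation, translation and respiration genes were lower at E41, by smaller amounts. Of 27 cell cycle genes, 0 were higher and 22 lower (0 and 26 list-adjusted), with a median of -0.57. The spindle factor TPX2 (-0.92 ± 0.09), cyclin CCNB2 (-0.99 ± 0.10) and the kinetochore gene CENPF (-0.92 ± 0.11) were among them. For cell cycle genes, camera gave adjusted p = 4.0e-05 (1.5e-09 to 0.0065) and adjusted p = 0.60 with an estimated correlation. Their median was -0.28 with library-size scaling alone. Of 18 ribosomal genes, 0 were higher and 16 lower (0 and 16 list-adjusted), with a median of -0.77. RPL7, whose reads may be shared with processed copies, changed by -1.16 ± 0.15. For ribosomal genes, camera gave adjusted p = 9.5e-05 (4.9e-08 to 0.016) and adjusted p = 0.60 with an estimated correlation. Their median was -0.48 with library-size scaling alone. Of 20 oxidative phosphorylation genes, 0 were higher and 18 lower (0 and 18 list-adjusted), with a median of -0.86. NDUFA4 (-1.28 ± 0.10) and COX5A (-1.19 ± 0.11), subunits of cytochrome oxidase, fell. For oxidative phosphorylation genes, camera gave adjusted p = 4.3e-07 (2.2e-10 to 0.0022) and adjusted p = 0.43 with an estimated correlation. Their median was -0.57 with library-size scaling alone. Of 13 mitochondrially encoded genes, 1 was higher and 9 lower (1 and 9 list-adjusted), with a median of -0.83. For mitochondrially encoded genes, camera gave adjusted p = 0.0055 (0.00017 to 0.018) and adjusted p = 0.60 with an estimated correlation. Their median was -0.54 with library-size scaling alone.

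Fibroblast, limb position, Wnt target and BMP target genes were higher at E41. Of 26 fibroblast genes, 13 were higher and 0 lower (15 and 1 list-adjusted), with a median of 0.63. PRRX2 (1.96 ± 0.13), PRRX1 (1.35 ± 0.22) and OSR2 (1.41 ± 0.11) rose. For fibroblast genes, camera gave adjusted p = 0.00039 (3.1e-06 to 0.032) and adjusted p = 0.60 with an estimated correlation. Their median was 1.0 without WT E41 replicate 1 and 0.42 without WT E41 replicate 2. Of 14 Wnt targets, 8 were higher and 0 lower (8 and 0 list-adjusted), with a median of 0.98. AXIN2 rose by 1.59 ± 0.25 and SP5 by 2.37 ± 0.39. For Wnt targets, camera gave adjusted p = 0.0055 (7.3e-05 to 0.046) and adjusted p = 0.60 with an estimated correlation. Their median was 1.49 without WT E41 replicate 2. Of 18 limb position genes, 5 were higher and 1 lower (5 and 1 list-adjusted), with a median of 1.00. The hindlimb factor PITX1 rose by 1.96 ± 0.25 and SHOX2 by 1.19 ± 0.15. For limb position genes, camera gave adjusted p = 0.017 (0.00020 to 0.043) and adjusted p = 0.16 with an estimated correlation. Of 16 BMP and TGF-beta targets, 6 were higher and 1 lower (6 and 1 list-adjusted), with a median of 0.72. ID4 (3.03 ± 0.27), ID2 (0.88 ± 0.11) and the BMP inhibitor SMAD6 (1.87 ± 0.28) rose. For BMP and TGF-beta targets, camera gave adjusted p = 0.043 (0.0069 to 0.094) and adjusted p = 0.28 with an estimated correlation. BMP and TGF-beta targets lost the call without WT E41 replicate 2 (0.065) and KO E41 replicate 2 (0.094) and with limma-voom and library-size scaling alone.

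Vessel, blood and stress-response genes also moved at E41. Of 18 endothelial genes, 6 were higher and 0 lower (6 and 0 list-adjusted), with a median of 0.41. The endothelial factor ERG (1.33 ± 0.18) and EGFL7 (1.76 ± 0.24) rose. For endothelial genes, camera gave adjusted p = 0.014 (0.00024 to 0.11) and adjusted p = 0.66 with an estimated correlation. Endothelial genes lost the call without WT E41 replicate 2 (0.073) and with fry. Their median was 0.70 with library-size scaling alone, 0.70 without WT E41 replicate 1 and 0.27 without WT E41 replicate 2. Of 16 smooth muscle and pericyte genes, 1 was higher and 7 lower (1 and 7 list-adjusted), with a median of -0.42. The actin ACTA2 changed by -3.76 ± 0.14 and the pericyte receptor PDGFRB by 1.5 ± 0.20. For smooth muscle and pericyte genes, camera gave adjusted p = 0.036 (0.0046 to 0.098) and adjusted p = 0.60 with an estimated correlation. Smooth muscle and pericyte genes lost the call without WT E41 replicate 1 (0.098) and KO E41 replicate 1 (0.052) and with limma-voom and the 1 CPM filter. Their median was -0.13 with library-size scaling alone, -0.16 with no low-count filter and -0.22 without WT E41 replicate 1. Of 13 red blood cell genes, 4 were higher and 0 lower (3 and 0 list-adjusted), with a median of 1.59. The transferrin receptor TFR2 rose by 2.04 ± 0.33. For red blood cell genes, camera gave adjusted p = 0.046 (0.0071 to 0.18) and adjusted p = 0.66 with an estimated correlation. Red blood cell genes lost the call without WT E41 replicate 2 (0.11) and KO E41 replicate 2 (0.083) and with DESeq2, limma-voom, library-size scaling alone, TMM from genes outside the muscle lists, the 1 CPM filter, thinned counts and fry. Of 12 immediate early genes, 6 were higher and 1 lower (6 and 1 list-adjusted), with a median of 1.49. JUN (1.93 ± 0.26) and IER3 (1.96 ± 0.24) rose, against the chaperone HSPA8 at -1.19 ± 0.14. For immediate early genes, camera gave adjusted p = 0.032 (1.5e-05 to 0.090) and adjusted p = 0.60 with an estimated correlation. Immediate early genes lost the call without WT E41 replicate 2 (0.090) and with library-size scaling alone. Their median was 0.77 without KO E41 replicate 2.

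In all, 3143 genes were higher and 3535 lower at E41. Of 35 lists, 21 passed the camera test at E41, and 9 with an estimated correlation. The gene count was 3927 without KO E41 replicate 1 and 4036 without KO E41 replicate 2. With library sizes alone as the scaling, the median of all genes shifted by 0.290 and 5780 of 7850 changed genes were higher, or 73.6%, against 47.1% with TMM. The largest rises by rule were of the cadherins PCDH8 (4.11 ± 0.55) and CDH9 (3.79 ± 0.76), LRTM2 (3.86 ± 0.41), the endocytic adaptor PACSIN1 (3.53 ± 0.47), the somatostatin receptor SSTR1 (3.43 ± 0.55), ESPNL (3.00 ± 0.38), the pentraxin NPTX1 (2.99 ± 0.46) and ID4. Their adjusted p ran from 0.00018 to 0.0070. For CDH9, the adjusted p of 0.0070 became 0.059 without WT E41 replicate 1 (8.7e-06 to 0.13 over alternatives).

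**Figure D2:**
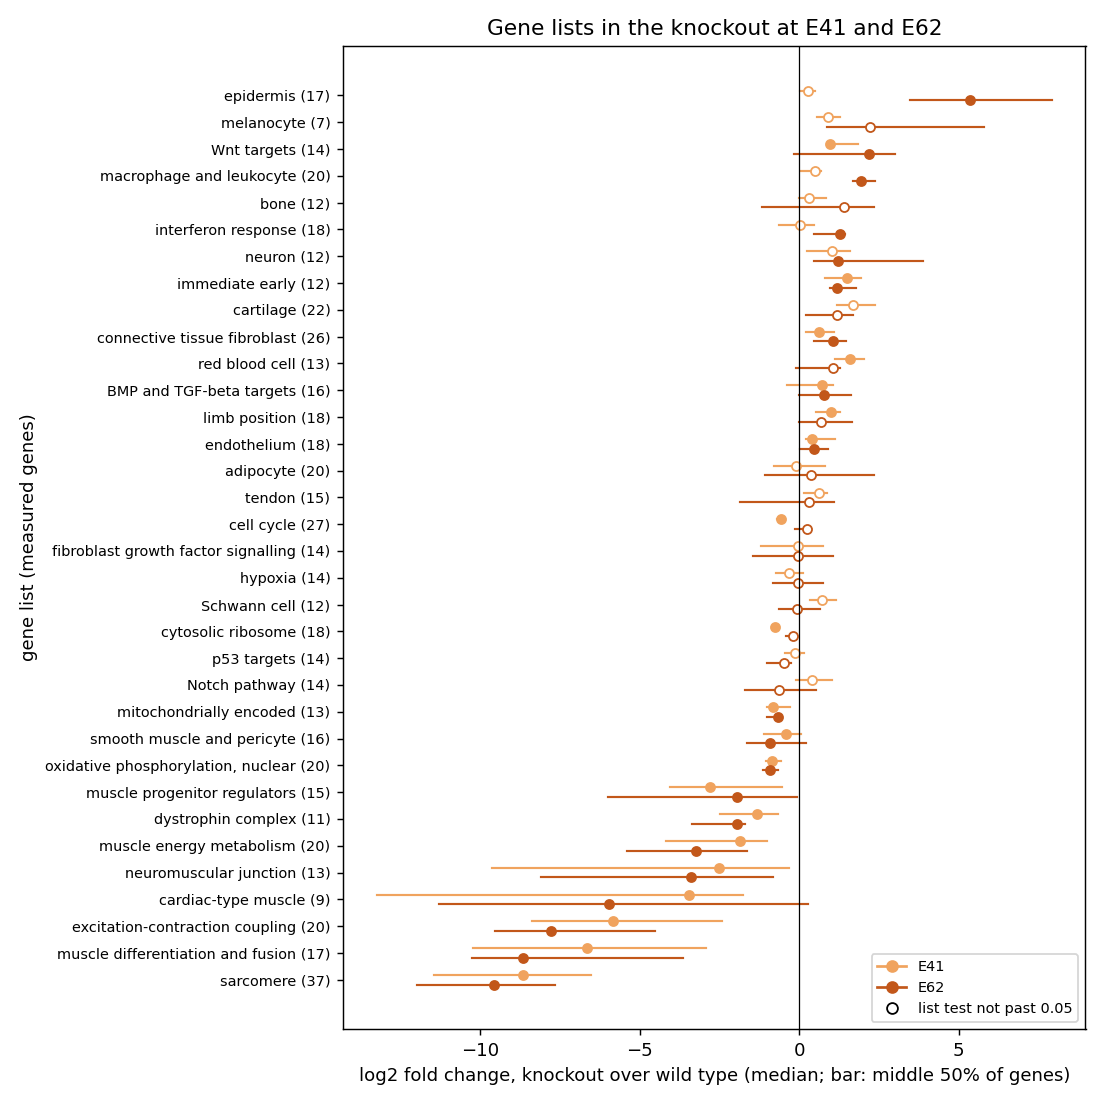
Median log2 fold change of each list's measured genes, knockout over wild type, at E41 and E62. Medians have genes with 3 counts or fewer in a group at their floor or ratio. Bars span the middle 50% of the fitted gene values, and filled points passed camera at 0.05. The sarcomere lies at -8.64 at E41 and -9.57 at E62.

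At E62 all 37 of 37 measured sarcomere genes were lower in the knockout (0 and 37 list-adjusted), with a median of -9.57. The skeletal actin ACTA1 changed by -16.30 ± 0.52, ACTC1 by -15.13 ± 0.38 and the myosin binding protein MYBPC1 by -13.58 ± 0.25. CSRP3, a muscle LIM protein of the Z-disc, was at least 20008-fold lower and the Z-disc gene MYPN at least 6912-fold lower. VGLL2, a cofactor of muscle transcription, was at least 10990.4-fold lower. Of 17 differentiation and fusion genes, 0 were higher and 15 lower (0 and 15 list-adjusted), with a median of -8.66. CDH15 changed by -9.76 ± 0.18 and KLHL40 by -8.10 ± 0.14. Of 20 excitation-contraction coupling genes, 0 were higher and 19 lower (0 and 19 list-adjusted), with a median of -7.78. SLN changed by -12.04 ± 0.20 and the release channel RYR3 by -4.53 ± 0.29. Of 11 dystrophin complex genes, 0 were higher and 11 lower (0 and 11 list-adjusted), with a median of -1.95. DMD changed by -4.21 ± 0.17.

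Of 20 energy metabolism genes, 1 was higher and 17 lower at E62 (1 and 18 list-adjusted), with a median of -3.22. CKM changed by -11.02 ± 0.22, ENO3 by -6.95 ± 0.25 and PDK4 by 1.44 ± 0.23. The neuromuscular junction had 9 of 13 genes lower and 1 higher (1 and 10 list-adjusted), with a median of -3.37. MUSK changed by -9.31 ± 0.18, CHRND by -8.59 ± 0.23 and AGRN by 1.36 ± 0.19. Cardiac-type muscle had 6 of 9 lower and 1 higher (1 and 6 list-adjusted), with a median of -5.95. Their median was -0.45 with no low-count filter and -10.99 with the 1 CPM filter. HAND2 rose by 1.77 ± 0.36. Camera adjusted p of these muscle lists at E62 lay between 8.5e-141 for the sarcomere and 3.4e-12 for the cardiac-type genes. With an estimated correlation they lay between adjusted p = 0.0025 for differentiation and 0.012 for the junction. Of 15 muscle progenitor regulators, 1 was higher and 10 lower (1 and 10 list-adjusted), with a median of -1.93. LBX1 changed by -7.65 ± 0.47 and PITX3 by -6.86 ± 0.29. For muscle progenitor regulators, camera gave adjusted p = 0.00072 (1.6e-07 to 0.0059) and adjusted p = 0.067 with an estimated correlation. Of 20 oxidative phosphorylation genes, 1 was higher and 18 lower (1 and 18 list-adjusted), with a median of -0.92. For oxidative phosphorylation genes, camera gave adjusted p = 8.9e-05 (1.1e-07 to 0.0023) and adjusted p = 0.50 with an estimated correlation. Of 13 mitochondrially encoded genes, 0 were higher and 12 lower (0 and 13 list-adjusted), with a median of -0.66. For mitochondrially encoded genes, camera gave adjusted p = 0.022 (0.00017 to 0.062) and adjusted p = 0.68 with an estimated correlation. Mitochondrially encoded genes lost the call without KO E62 replicate 2 (0.062) and with the 1 CPM filter. Their median was -0.35 with library-size scaling alone.

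Immune genes were higher in the knockout at E62. Of 20 macrophage and leukocyte genes, 18 were higher and 1 lower (18 and 1 list-adjusted), with a median of 1.95. The complement subunits C1QA (1.92 ± 0.13), C1QB (2.35 ± 0.20) and C1QC (2.48 ± 0.21) and the lysosomal protein gene LAPTM5 (2.36 ± 0.10) rose. The integrin gene ITGAM changed by -1.09 ± 0.37. For ITGAM, the adjusted p of 0.041 became 0.11 without WT E62 replicate 1, 0.12 without WT E62 replicate 2 and 0.16 without KO E62 replicate 1 (0.016 to 0.16 over alternatives). For macrophage and leukocyte genes, camera gave adjusted p = 1.4e-08 (2.0e-15 to 0.0026) and adjusted p = 0.30 with an estimated correlation. Of 18 interferon response genes, 11 were higher and 0 lower (11 and 0 list-adjusted), with a median of 1.29. The antiviral genes IFIT1 (3.03 ± 0.39), BST2 (1.43 ± 0.17) and IFI44L (1.28 ± 0.18) rose. IFIT genes resemble each other, and reads shared between them leave their single values uncertain. For interferon response genes, camera gave adjusted p = 0.015 (0.0024 to 0.025) and adjusted p = 0.30 with an estimated correlation. At E41 the macrophage list had 5 genes higher and 1 lower (5 and 1 list-adjusted), with a median of 0.51. For macrophage and leukocyte genes at E41, camera gave adjusted p = 0.084 (0.00010 to 0.54). Macrophage and leukocyte genes passed the test without WT E41 replicate 1 (0.00010) and KO E62 replicate 1 (0.043) and with limma-voom and no low-count filter. Their median was 1.08 without WT E41 replicate 1 and 0.19 without WT E41 replicate 2. The interferon list at E41 had 2 higher and 4 lower (2 and 4 list-adjusted, camera adjusted p = 0.54), with a median of 0.03 (-0.01 to 0.33 over alternatives) and a mean and test of the opposite sign.

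Fibroblast, BMP target, Wnt target and endothelial genes were higher at E62, and smooth muscle genes lower. Of 26 fibroblast genes, 17 were higher and 1 lower (17 and 1 list-adjusted), with a median of 1.08. PRRX1 rose by 1.95 ± 0.22, OSR2 by 2.06 ± 0.11 and the growth factor receptor PDGFRA by 1.38 ± 0.10. For fibroblast genes, camera gave adjusted p = 3.7e-05 (2.7e-08 to 0.0090) and adjusted p = 0.50 with an estimated correlation. Of 16 BMP and TGF-beta targets, 7 were higher and 3 lower (7 and 3 list-adjusted), with a median of 0.77. The BMP antagonist GREM1 rose by 8.07 ± 0.43. For BMP and TGF-beta targets, camera gave adjusted p = 0.0062 (0.0013 to 0.039) and adjusted p = 0.12 with an estimated correlation. Of 14 Wnt targets, 9 were higher and 1 lower (9 and 2 list-adjusted), with a median of 2.20. SP5 rose by 2.82 ± 0.42 and the R-spondin receptor LGR5 by 2.79 ± 0.47. For Wnt targets, camera gave adjusted p = 0.031 (6.5e-06 to 0.089) and adjusted p = 0.68 with an estimated correlation. Wnt targets lost the call with limma-voom, library-size scaling alone and fry. Their median was 1.16 without KO E62 replicate 1. Of 18 endothelial genes, 8 were higher and 0 lower (7 and 0 list-adjusted), with a median of 0.48. ERG rose by 1.67 ± 0.18. For endothelial genes, camera gave adjusted p = 0.033 (5.0e-06 to 0.28) and adjusted p = 0.80 with an estimated correlation. Endothelial genes lost the call without KO E62 replicate 2 (0.28) and with library-size scaling alone and fry. Their median was 0.78 with library-size scaling alone, 0.84 without KO E62 replicate 1 and 0.03 without KO E62 replicate 2. Of 16 smooth muscle and pericyte genes, 3 were higher and 9 lower (3 and 9 list-adjusted), with a median of -0.90. ACTA2 changed by -2.97 ± 0.13 and PDGFRB by 0.88 ± 0.19. For smooth muscle and pericyte genes, camera gave adjusted p = 0.033 (0.0010 to 0.077) and adjusted p = 0.57 with an estimated correlation. Smooth muscle and pericyte genes lost the call without KO E62 replicate 1 (0.077) and with limma-voom, the 1 CPM filter and only the groups compared. Their median was -0.59 with library-size scaling alone. Of 12 immediate early genes, 6 were higher and 1 lower (7 and 1 list-adjusted), with a median of 1.2. JUN changed by 1.74 ± 0.26 and HSPA8 by -1.04 ± 0.14. For immediate early genes, camera gave adjusted p = 0.041 (0.0030 to 0.079) and adjusted p = 0.50 with an estimated correlation. Immediate early genes lost the call without KO E62 replicate 2 (0.079) and with DESeq2 and library-size scaling alone.

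Some epidermal and neuronal genes were higher in the knockout at E62. Of 17 epidermal genes, 4 were higher and 0 lower (4 and 0 list-adjusted), with a median of 5.36. The desmosome gene DSP changed by 6.55 ± 1.24, DSG3, its partner, was 195-fold higher (interval 66.6 to 947) and keratin KRT18 41-fold higher (interval 7.15 to 1642). The epidermal median per library, on the log2 scale relative to each gene's mean, was 2.02 in KO E62 replicate 1 and -2.58 in replicate 2, against -4.60 and -3.64 in wild type and 1.65 to 2.79 in the E41 libraries. For epidermal genes, camera gave adjusted p = 0.032 (1.9e-12 to 0.20) and adjusted p = 0.80 with an estimated correlation. Epidermal genes lost the call without KO E62 replicate 1 (0.14) and with limma-voom, library-size scaling alone and fry. Their fitted median of 5.23 was 1.28 without KO E62 replicate 1. For DSP, the adjusted p of 0.011 became 0.085 without WT E62 replicate 1 and 0.077 without WT E62 replicate 2 (7.4e-13 to 0.17 over alternatives). For DSG3, the adjusted p of 0.011 became 0.083 without WT E62 replicate 1 and 0.081 without WT E62 replicate 2 (3.9e-08 to 0.29 over alternatives). For KRT18, the adjusted p of 0.012 became 0.080 without WT E62 replicate 1 (0.0014 to 0.12 over alternatives). Of 12 neuronal genes, 6 were higher and 0 lower (6 and 0 list-adjusted), with a median of 1.21. The secretory protein gene SCG3 rose by 3.78 ± 0.34 and the axonal gene STMN2 by 4.14 ± 0.46. Neuronal medians per library were 0.34 and -0.42 in the knockout and -1.14 and -1.45 in wild type. For neuronal genes, camera gave adjusted p = 0.017 (0.0027 to 0.064) and adjusted p = 0.36 with an estimated correlation. Neuronal genes lost the call with library-size scaling alone. Their fitted median of 2.33 was 1.52 with thinned counts.

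In all, 3573 genes were higher and 4455 lower at E62, and 6694 changed without KO E62 replicate 2. Of 35 lists, 21 passed the camera test at E62, and 8 with an estimated correlation. With library sizes alone the median of all genes shifted by 0.305 and 6156 of 8873 changed genes were higher, or 69.4% against 44.5% with TMM. Among the largest rises by rule, GLIS1 was at least 102-fold higher and IRX2 812-fold higher (interval 146 to 32093). SPTLC3 was 763-fold higher (interval 137 to 30139) and PCSK2 at least 24.4-fold higher. GREM1 and RSPO1 (262-fold, interval 89.4 to 1271) belonged to the set. SULT1E1 was at least 56.0-fold higher and the epidermal gene DSC1 299.8-fold higher (interval 102 to 1455). GREM1 aside, these genes had 28 to 291 counts in wild type at E41 and 0 to 3 at E62, a fall like that of epidermal genes. Skin content was not tested for them. For SULT1E1, the adjusted p of 0.042 became 0.076 to 0.12 without any 1 library outside KO E62 (6.7e-05 to 0.18 over alternatives). For DSC1, the adjusted p of 0.049 became 0.073 to 0.22 without any 1 library outside KO E62 (1.8e-05 to 0.53 over alternatives).

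**Figure D3:**
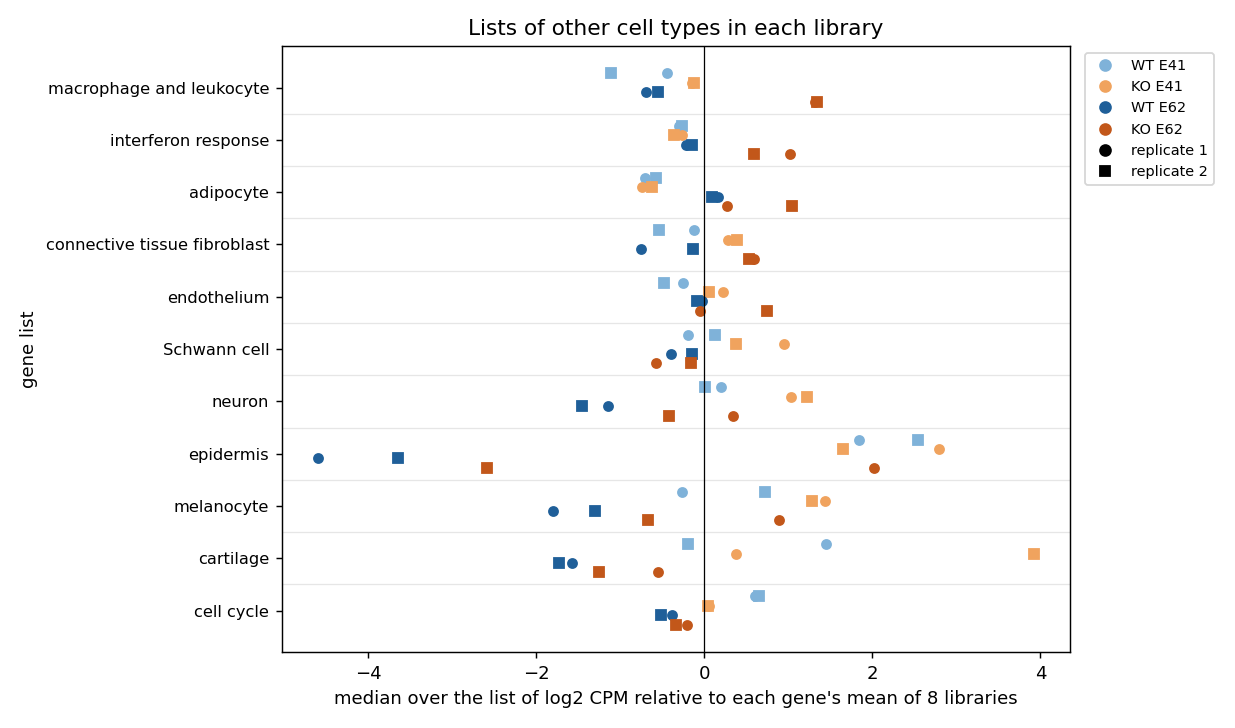
Median log2 CPM of each list relative to each gene's mean over the 8 libraries, 1 point per library. Macrophage genes lie at 1.31 and 1.35 in the knockout E62 libraries, while epidermal genes lie at 2.02 in replicate 1 and -2.58 in replicate 2.

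The genotype comparisons share no libraries, and their calls were set against each other. A rise at both stages was found for 1286 genes, against 659.8 for independent lists (Fisher's exact test over genes, which are not independent replicates, p = 1.0e-179). A fall at both was found for 2144, against 925.3. A rise at E41 with a fall at E62 was found for 452 genes, against 822.7 (Fisher's exact p = 1.8e-68), and the opposite for 176, against 742.1 (exact p = 5.6e-191), both fewer than independent lists would share. The 3430 genes changed in the same direction were 2245 without KO E41 replicate 1 and 2243 without KO E41 replicate 2. Across genes the log2 changes of both stages had Pearson's r = 0.604 and Spearman's rho = 0.477 over 17020 genes.

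The genotype effect itself differed between the stages for 4553 genes, 1913 with a higher and 2640 with a lower effect at E62. That count was 2499 without KO E41 replicate 1 and 2685 without KO E41 replicate 2. By camera it differed for 13 of 35 lists, and for 0 with an estimated correlation. Of 27 cell cycle genes, 17 had a higher effect at E62 and 0 a lower effect (19 and 0 list-adjusted), with a median log2 difference of 0.74. CCNB2 differed by 1.34 ± 0.14 and CENPF by 1.54 ± 0.16, and both were lower in the knockout at E41 and higher at E62 (0.35 ± 0.10 and 0.62 ± 0.11). For cell cycle genes, camera gave adjusted p = 8.1e-10 (5.0e-12 to 0.018) and adjusted p = 0.53 with an estimated correlation. At E62 the cell cycle list had 9 genes higher and 0 lower (8 and 0 list-adjusted), with a median of 0.25 (0.16 to 0.55 over alternatives). For cell cycle genes at E62, camera gave adjusted p = 0.16 (0.018 to 0.42). Cell cycle genes passed the test without WT E62 replicate 1 (0.018) and with limma-voom and library-size scaling alone. Of 18 ribosomal genes, 6 had a higher effect at E62 and 0 a lower effect (9 and 0 list-adjusted), with a median log2 difference of 0.52. For ribosomal genes, camera gave adjusted p = 0.00076 (2.3e-05 to 0.13) and adjusted p = 0.93 with an estimated correlation. Ribosomal genes lost the call with fry. At E62 the ribosomal list had 0 higher and 6 lower (0 and 0 list-adjusted, median -0.19 or -0.33 to 0.11 over alternatives, camera adjusted p = 0.64).

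Immune genes had a higher genotype effect at E62 than at E41. Of 20 macrophage and leukocyte genes, 11 had a higher effect at E62 and 0 a lower effect (12 and 0 list-adjusted), with a median log2 difference of 1.67. C1QC differed by 2.51 ± 0.29 and LAPTM5 by 1.93 ± 0.14. For macrophage and leukocyte genes, camera gave adjusted p = 9.0e-08 (1.3e-20 to 0.052) and adjusted p = 0.53 with an estimated correlation. Macrophage and leukocyte genes lost the call with fry. Their median was 1.05 without WT E41 replicate 1. Of 18 interferon response genes, 8 had a higher effect at E62 and 0 a lower effect (9 and 0 list-adjusted), with a median log2 difference of 1.07. IFIT1 differed by 3.95 ± 0.56, IFIT3 by 2.63 ± 0.34 and IFIT2 by 2.10 ± 0.24. For interferon response genes, camera gave adjusted p = 0.00011 (2.9e-05 to 0.0060) and adjusted p = 0.19 with an estimated correlation. Their median was 0.70 without KO E62 replicate 1. Of 20 excitation-contraction coupling genes, 0 had a higher effect at E62 and 12 a lower effect (0 and 13 list-adjusted), with a median log2 difference of -2.07. RYR3 differed by -3.84 ± 0.37. For excitation-contraction coupling genes, camera gave adjusted p = 9.0e-08 (6.1e-09 to 0.0040) and adjusted p = 0.16 with an estimated correlation. By rule, GLIS1, SPTLC3 and DSG3 differed most upward, with 0, 1 and 3 counts in the wild-type E62 libraries together, and RANBP3L by 8.03 ± 0.77. Downward, LRRC38, an auxiliary potassium channel subunit, differed by -6.11 ± 0.97 and DLK2 by -6.06 ± 0.83. VGLL2 and PAX7, with 0 and 1 counts in the knockout at E62, also differed downward. For PAX7, the adjusted p of 0.025 became 0.051 to 0.097 without any 1 library outside KO E41 (2.1e-05 to 0.097 over alternatives). For DSG3, the adjusted p of 0.032 became 0.071 to 0.13 without any 1 library other than KO E41 replicate 1, KO E62 replicate 1 and KO E62 replicate 2 (2.5e-05 to 0.34 over alternatives).

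In wild type, sarcomere and coupling genes were higher at E62 than at E41, and cell cycle genes were lower in both genotypes. Of 27 cell cycle genes, 0 were higher and 27 lower (0 and 27 list-adjusted), with a median of -1.0. TOP2A changed by -1.38 ± 0.10 and MCM6 by -1.37 ± 0.09. For cell cycle genes, camera gave adjusted p = 4.0e-23 (8.6e-27 to 0.0013) and adjusted p = 0.20 with an estimated correlation. Of 27 cell cycle genes, 1 was higher and 11 lower in the knockout (1 and 12 list-adjusted), with a median of -0.30. For cell cycle genes in the knockout, camera gave adjusted p = 0.011 (0.00062 to 0.13) and adjusted p = 0.90 with an estimated correlation. Cell cycle genes lost the call without KO E62 replicate 2 (0.13) and with the 1 CPM filter and fry. Of 20 excitation-contraction coupling genes, 17 were higher and 0 lower (19 and 0 list-adjusted), with a median of 1.80. RYR1 rose by 1.97 ± 0.17 and SLN by 2.63 ± 0.12. For excitation-contraction coupling genes, camera gave adjusted p = 3.1e-19 (7.7e-23 to 0.00046) and adjusted p = 0.052 with an estimated correlation. Of 37 sarcomere genes, 29 were higher and 0 lower (29 and 0 list-adjusted), with a median of 1.23. MYBPC1 rose by 2.26 ± 0.15. For sarcomere genes, camera gave adjusted p = 1.0e-17 (9.5e-22 to 0.0018) and adjusted p = 0.11 with an estimated correlation. The neuromuscular junction had 1 of 13 genes higher and 3 lower (1 and 2 list-adjusted), with a median of -0.41 (-0.42 to -0.24 over alternatives) and camera adjusted p = 0.41 (0.19 to 0.55). Of 17 epidermal genes, 0 were higher and 7 lower (0 and 8 list-adjusted), with a median of -6.18. For epidermal genes, camera gave adjusted p = 1.5e-05 (1.1e-29 to 0.054) and adjusted p = 0.58 with an estimated correlation. Epidermal genes lost the call with fry. Epidermal medians per library were 1.84 and 2.54 at E41 and -4.60 and -3.64 at E62, and melanocyte genes, also of skin, had a median of -2.37 (-2.56 to -0.24 over alternatives) (camera adjusted p = 0.16). In all, 6782 genes changed with stage in wild type, 3373 up and 3409 down, and 4491 without WT E62 replicate 2. Of 35 lists, 20 passed the camera test, 10 upward and 10 downward, and 0 with an estimated correlation.

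The largest rises in wild type by rule were of PLIN4 (5.37 ± 1.28), CA3 (5.22 ± 0.37), RXFP1 (5.09 ± 1.16) and CPA5 (4.76 ± 0.43). For PLIN4, the adjusted p of 0.022 became 0.11 without WT E41 replicate 1, 0.10 without WT E41 replicate 2 and 0.078 without WT E62 replicate 2 (0.0010 to 0.11 over alternatives). For RXFP1, the adjusted p of 0.014 became 0.058 without WT E62 replicate 2 (1.1e-06 to 0.058 over alternatives). The largest falls were GABRP (at least 2206-fold), SERPINB5 (7673-fold, interval 1376 to 303116), HEPHL1 (3629.9-fold, interval 651 to 143436) and SERPINI2 (at least 166-fold). Epidermal genes fell likewise, and skin content was not tested for these genes in either genotype. For SERPINB5, the adjusted p of 0.043 became 0.073 to 0.19 without any 1 library outside KO E62 (1.9e-07 to 0.43 over alternatives). For HEPHL1, the adjusted p of 0.017 became 0.10 without WT E62 replicate 1 and 0.11 without WT E62 replicate 2 (9.6e-09 to 0.24 over alternatives). For SERPINI2, the adjusted p of 0.0497 became 0.099 to 0.15 without any 1 library outside KO E62 (3.6e-05 to 0.15 over alternatives).

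In the knockout, immune genes were higher at E62 than at E41. In both genotypes camera called fat genes up and Wnt targets and cartilage genes down, though few cartilage genes passed singly. Of 20 macrophage and leukocyte genes, 15 were higher and 0 lower (16 and 0 list-adjusted), with a median of 1.57. For macrophage and leukocyte genes, camera gave adjusted p = 2.9e-13 (2.9e-23 to 0.034) and adjusted p = 0.64 with an estimated correlation. Of 18 interferon response genes, 9 were higher and 0 lower (12 and 0 list-adjusted), with a median of 1.21. For interferon response genes, camera gave adjusted p = 1.1e-07 (1.7e-10 to 0.0076) and adjusted p = 0.36 with an estimated correlation. Of 20 adipocyte genes, 10 were higher and 2 lower (10 and 2 list-adjusted), with a median of 1.10. ADIPOQ (7.04 ± 0.99), FABP4 (5.6 ± 0.32), PPARG (3.22 ± 0.32) and EBF2 (1.82 ± 0.11) rose. For adipocyte genes, camera gave adjusted p = 1.7e-05 (5.4e-07 to 0.065) and adjusted p = 0.77 with an estimated correlation. Adipocyte genes lost the call with fry. Their median was 0.47 with the 1 CPM filter. Of 20 adipocyte genes, 9 were higher and 2 lower in wild type (9 and 2 list-adjusted), with a median of 0.86. For adipocyte genes in wild type, camera gave adjusted p = 0.015 (0.0014 to 0.051) and adjusted p = 0.58 with an estimated correlation. Adipocyte genes lost the call with limma-voom. Their median was 1.29 without WT E41 replicate 1. Of 22 cartilage genes, 0 were higher and 4 lower (0 and 3 list-adjusted), with a median of -4.40. For cartilage genes, camera gave adjusted p = 0.0059 (3.2e-13 to 0.16) and adjusted p = 0.90 with an estimated correlation. Cartilage genes lost the call without KO E41 replicate 2 (0.077) and with fry. Their median was -1.24 without KO E41 replicate 2. Medians per library were 0.38 and 3.92 at E41 and -0.54 and -1.25 at E62. Of 22 cartilage genes, 1 was higher and 3 lower in wild type (1 and 2 list-adjusted), with a median of -2.16. For cartilage genes in wild type, camera gave adjusted p = 0.021 (0.00035 to 0.20) and adjusted p = 0.76 with an estimated correlation. Cartilage genes lost the call with limma-voom and fry. Their fitted median of -2.46 was -1.22 without WT E41 replicate 1. Of 14 Wnt targets, 0 were higher and 7 lower (0 and 9 list-adjusted), with a median of -1.04. For Wnt targets, camera gave adjusted p = 0.0038 (3.0e-07 to 0.093) and adjusted p = 0.90 with an estimated correlation. Wnt targets lost the call with fry. Their median was -1.61 without KO E62 replicate 1. Of 14 Wnt targets, 1 was higher and 7 lower in wild type (1 and 8 list-adjusted), with a median of -1.02. For Wnt targets in wild type, camera gave adjusted p = 0.0080 (3.1e-05 to 0.075) and adjusted p = 0.59 with an estimated correlation. Wnt targets lost the call with limma-voom and fry.

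The largest rises in the knockout by rule were of ADIPOQ and FABP4, and of the microfibrillar collagens COL6A5 (6.86 ± 0.82) and COL6A6 (5.39 ± 0.65). The largest falls were of GABRP (-7.55 ± 1.04), INSYN2B (-7.40 ± 0.62), the patterning factor MAB21L2 (-6.82 ± 0.44) and PAX7, 141-fold lower (interval 24.7 to 5616). For GABRP, the adjusted p of 0.013 became 0.070 without KO E41 replicate 1 and 0.054 without KO E41 replicate 2 (9.0e-08 to 0.070 over alternatives). For PAX7, the adjusted p of 0.020 became 0.086 without KO E62 replicate 1 and 0.081 without KO E62 replicate 2 (2.1e-05 to 0.086 over alternatives). In all, 5126 genes changed with stage in the knockout, 2065 up and 3061 down, and 8 of 35 lists passed the camera test, 0 of them with an estimated correlation. The gene count was 1906 without KO E41 replicate 1, 2245 without KO E41 replicate 2 and 2970 without KO E62 replicate 2. A rise with stage in both genotypes was found for 692 genes, against 409.2 for independent lists, and a fall in both for 1034, against 613.1. A rise in wild type and a fall in the knockout was found for 638, against 606.6, and the opposite for 185, against 413.6.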

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

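All tests of explanations in this part were chosen after the results were seen, while the tests of the difference between stages were fixed beforehand. For each gene and list here the effect of the knockout differed between E62 and E41 by edgeR or camera. Values are the log2 effect at E62 minus that at E41. Some muscle genes had a lower effect at E62, that is they lay further below wild type in the knockout than at E41. They were CKM -2.63, CDH15 -2.35, KLHL40 -1.72, SLN -2.39, RYR3 -3.84, MYBPC1 -2.13, DMD -1.97, ENO3 -2.95 and LBX1 -3.94 (adjusted p 0.00092 to 0.0042). CA3 -4.95 and CPA5 -2.55 also had a lower effect (adjusted p 0.0014 to 0.016). ACTC1 -1.67 had an adjusted p of 0.020, which became 0.053 without WT E41 replicate 1 and 0.12 without KO E41 replicate 1 (3.5e-05 to 0.12 over alternatives). The differentiation list had 0 higher and 8 lower of 17 (0 and 9 list-adjusted), median -1.14. In muscle differentiation and fusion, camera gave adjusted p = 0.00039 (0.00011 to 0.0066) and adjusted p = 0.16 with an estimated correlation. Their median was -0.73 without WT E62 replicate 2. The sarcomere list had 1 higher and 12 lower of 37 (1 and 14 list-adjusted), median -1.10, or -0.93 with genes near 0 at their floor or ratio. In sarcomere, camera gave adjusted p = 0.0019 (0.00013 to 0.042) and adjusted p = 0.61 with an estimated correlation. Energy metabolism had 0 higher and 8 lower of 20 (0 and 11 list-adjusted), median -0.68. In muscle energy metabolism, camera gave adjusted p = 4.5e-05 (4.9e-06 to 0.0040) and adjusted p = 0.19 with an estimated correlation. The dystrophin complex had 0 higher and 7 lower of 11 (0 and 8 list-adjusted), median -0.97. In dystrophin complex, camera gave adjusted p = 0.00039 (0.00013 to 0.0026) and adjusted p = 0.16 with an estimated correlation. Coupling genes had a median of -2.07. Other muscle lists did not pass this test: progenitor regulators 1 higher and 4 lower of 15 (adjusted p = 0.48), junction 2 higher and 2 lower of 13 (adjusted p = 0.88), cardiac-type 0 higher and 2 lower of 9 (adjusted p = 0.88) and targeted genes 0 higher and 0 lower of 3 (adjusted p = 0.88), or 2 and 4, 2 and 2, 0 and 2 and 0 and 0 list-adjusted. The progenitor list passed it without KO E41 replicate 1 (0.046) and with fry.

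Proliferation genes differed upward: CCNB2 1.34, CENPF 1.54, TPX2 1.17, TOP2A 0.75 and MCM6 0.98 (adjusted p 0.0011 to 0.0065), with a list median of 0.74. The ribosomal gene RPL7 1.45 (adjusted p = 0.0029) differed upward, and its list had a median of 0.52. Immune genes did as well: C1QA 1.24, C1QB 1.92, C1QC 2.51, LAPTM5 1.93, IFIT1 3.95, IFIT2 2.10, IFIT3 2.63, BST2 1.37 and IFI44L 1.27 (adjusted p 0.00054 to 0.011), with list medians of 1.67 for macrophages and 1.07 for the interferon response. Of connective tissue and BMP genes, PDGFRA 0.84, OSR2 0.65, GREM1 6.56 and COL6A6 2.96 differed upward (adjusted p 0.00099 to 0.044). Fat genes PPARG 2.40, FABP4 2.05 and EBF2 1.26 did so too (adjusted p 0.0017 to 0.013). The camera test of the difference was not passed by their lists, which had these members past the threshold: fibroblast 6 higher and 2 lower of 26 (adjusted p = 0.17), BMP and TGF-beta 4 higher and 0 lower of 16 (adjusted p = 0.12), adipocyte 5 higher and 4 lower of 20 (adjusted p = 0.40) and smooth muscle 4 higher and 4 lower of 16 (adjusted p = 0.76). Adjusted over the list alone they were 6 and 2, 4 and 0, 6 and 5 and 4 and 4. The fibroblast list passed it without WT E41 replicate 2 (0.020) and WT E62 replicate 2 (0.0025). The BMP list passed it without WT E41 replicate 2 (0.044) and KO E41 replicate 2 (0.034). ID2 0.65 had an adjusted p of 0.016, which became 0.056 without WT E41 replicate 2 and 0.074 without KO E41 replicate 2 (0.0027 to 0.074 over alternatives). ACTA2 0.78 had 0.014, which became 0.056 without WT E41 replicate 1, 0.065 without KO E41 replicate 1, 0.063 without KO E41 replicate 2 and 0.054 without WT E62 replicate 2 (6.5e-05 to 0.065 over alternatives).

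Neuronal genes SCG3 2.95 and STMN2 3.84 differed upward (adjusted p 0.0040 to 0.0072). Their list had 4 higher and 0 lower of 12 (5 and 0 list-adjusted), median 1.92, or 1.30 with genes near 0 at their floor or ratio. In neuron, camera gave adjusted p = 0.038 (0.0062 to 0.22) and adjusted p = 0.61 with an estimated correlation. The neuron call ended without WT E62 replicate 2 (0.091) and KO E62 replicate 1 (0.22) and with limma-voom, no low-count filter, the replicate block and fry. Their median was 0.77 with no low-count filter. Schwann cell genes ERBB3 -2.01, FOXD3 -5.02 and SOX10 -1.85 differed downward (adjusted p 0.0011 to 0.024). The Schwann cell list had 1 higher and 5 lower of 12 (1 and 5 list-adjusted), median -1.06. In Schwann cell, camera gave adjusted p = 0.038 (0.0033 to 0.22) and adjusted p = 0.76 with an estimated correlation. The Schwann cell call ended without WT E41 replicate 1 (0.062), KO E41 replicate 1 (0.11), WT E62 replicate 2 (0.13) and KO E62 replicate 1 (0.22) and with limma-voom, no low-count filter and fry. Their median was -0.67 without KO E41 replicate 1 and -0.58 without WT E62 replicate 2. Notch genes JAG2 -3.08, NOTCH1 -2.31 and DLL1 -1.96 differed downward (adjusted p 0.00065 to 0.0075). The Notch list had 0 higher and 5 lower of 14 (0 and 5 list-adjusted), median -0.46. In Notch pathway, camera gave adjusted p = 0.0053 (7.0e-05 to 0.13) and adjusted p = 0.68 with an estimated correlation. The Notch pathway call ended without KO E62 replicate 1 (0.13) and with limma-voom and fry. Their median was -0.30 without KO E41 replicate 1 and -0.31 without KO E62 replicate 1.

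Limb and skeletal genes PITX1 -3.15, SOX6 -3.31 and MAB21L2 -2.73 differed downward (adjusted p 0.0020 to 0.016). SCX -2.85 had an adjusted p of 0.033, which became 0.057 to 0.12 without any 1 library other than WT E41 replicate 1, KO E41 replicate 1 and KO E62 replicate 1 (0.0048 to 0.12 over alternatives). BGLAP -3.02 had 0.014, which became 0.052 without KO E41 replicate 1 and 0.053 without WT E62 replicate 1 (0.0040 to 0.053 over alternatives). RUNX2 2.71 had 0.038, which became 0.058 to 0.13 without any 1 library outside KO E41 (0.00074 to 0.26 over alternatives). The lists of these tissues did not pass the test of the difference either: limb position 0 higher and 3 lower of 18 (adjusted p = 0.96), tendon 1 higher and 1 lower of 15 (adjusted p = 0.88), bone 2 higher and 1 lower of 12 (adjusted p = 0.42) and cartilage 1 higher and 1 lower of 22 (adjusted p = 0.85). Adjusted over the list alone these were 0 and 3, 0 and 0, 2 and 1 and 1 and 1. The bone list passed it without WT E41 replicate 1 (0.014) and the cartilage list passed it without KO E41 replicate 1 (0.023). Of the genes named for the size of their change, RANBP3L 8.03 differed upward and DLK2 -6.06, LRRC38 -6.11, ESPNL -2.67, LRTM2 -2.58 and SSTR1 -3.64 downward (adjusted p 0.00099 to 0.020). Where a group had 3 counts or fewer, the adjusted p of the difference is given without a size: GLIS1 (0.0038), IRX2 (0.0047), SPTLC3 (0.0075), VGLL2 (0.0098), PCSK2 (0.012) and RSPO1 (0.031). CHRND (0.011) became 0.12 without KO E41 replicate 2 and 0.051 without KO E62 replicate 1 (0.011 to 0.34 over alternatives). PAX7 (0.025) became 0.051 to 0.097 without any 1 library outside KO E41 (2.1e-05 to 0.097 over alternatives).

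The epidermal list had 3 higher and 0 lower of 17 (3 and 0 list-adjusted), median 5.72, or 6.01 with genes near 0 at their floor or ratio. In epidermis, camera gave adjusted p = 0.0023 (2.6e-17 to 0.34) and adjusted p = 0.93 with an estimated correlation. The epidermis call ended without KO E62 replicate 1 (0.22) and with limma-voom and fry. Their median was 0.91 without KO E62 replicate 1. DSP 6.51 had an adjusted p of 0.035, which became 0.055 to 0.13 without any 1 library outside KO E62 (1.9e-06 to 0.25 over alternatives). DSG3 (0.032) became 0.071 to 0.13 without any 1 library other than KO E41 replicate 1, KO E62 replicate 1 and KO E62 replicate 2 (2.5e-05 to 0.34 over alternatives). KRT18 (0.021) became 0.0504 to 0.088 without any 1 library other than WT E41 replicate 1, WT E41 replicate 2 and KO E62 replicate 2 (0.0012 to 0.13 over alternatives).

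Skin content that differs between the E62 samples may account for part of the epidermal difference. In the knockout at E62, replicate 1 over replicate 2 had a median log2 ratio of 5.73 for 17 epidermal genes, of which 15 were at least 4-fold higher, and of 1.56 for 7 melanocyte genes, from another skin cell type, of which 3 were. Replicate 1 (epidermal median 2.02) lay at the level of the 4 E41 libraries (1.65 to 2.79), so these values do not tell more skin in it from less skin or lower epidermal expression in the other E62 libraries. A genotype effect on epidermal genes stays open: replicate 2 lay at a median of 1.24 over the wild-type mean (quartiles -0.69 to 2.57), with 7 of 17 genes at least 4-fold higher.

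MYOD1 kept 0.617% of its wild-type level in the knockout at E41 and 0.801% at E62. Reads or cells carried over from wild type would bring abundant muscle transcripts at a like share, but of sarcomere genes more abundant than MYOD1, 20 of 26 at E41 and 25 of 28 at E62 lay below it in both knockout libraries, with 95% counting intervals apart (medians of all 0.176% and 0.0776%). These 76.9% and 89.3%, and 0 counts of MYF6, CSRP3 and VGLL2 at E62 against 7111, 31588 and 17351 in wild type, argue against carry-over as the source of all MYOD1 counts. An earlier test asked that under 5% of the genes keep the share, and 15.4% at E41 and 7.14% at E62 kept it, but carry-over rules out genes below the share and not genes above it, so that limit decides nothing. Transcription of the edited gene stays open at 0.801%, as no reads or genome were used here to place the counts on the transcript.

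Macrophage genes stood at a median log2 change of 1.95 in the knockout at E62. A loss of muscle RNA alone would raise other cell types alike. The endothelial median was 0.475 (0.84 without KO E62 replicate 1 and 0.03 without replicate 2). The difference from macrophage genes was 1.48 (permutation test over genes, which are not independent, p = 5.9e-04, 100000 permutations). Endothelium was picked with the list medians already known, so this p does not exclude a loss of muscle RNA. Fibroblast genes lay at 1.08 and Schwann cell genes at -0.06, and these were not tested against macrophage genes. Skin in replicate 1 is argued against, since its macrophage genes differed from those of replicate 2 by a median log2 of 0.036. A litter, dissection or library batch shared by both libraries stays open, as 0 of them carry another number in their names, and an effect of the genotype cannot be told apart from it.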

How the results depend on the processing

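All alternatives were chosen before the data were examined. Of the counts of changed genes and called lists, 189 alternative values lay within 1.5 times the original and 23 moved further. No gene or list reversed direction while called: 13790 gene values kept their side of the threshold, 1056 lost the call and 146 gained it, and of the list values 3233 kept it, 162 lost it and 69 gained it. Asking for at least a 2-fold change left 2472 genes at E41, 3910 at E62, 2327 for the difference between stages, 2730 for stage in wild type, 2162 for stage in the knockout and 1321 changed in the same direction at both stages. Without 1 library at a time, the count of genes ranged from 3927 to 6720 at E41, 5816 to 8131 at E62, 2499 to 4282 for the difference, 4491 to 6885 for stage in wild type, 1906 to 5022 for stage in the knockout and 2243 to 3265 for the same direction. In each such fit the lone library was assumed to vary like the other groups, and fewer residual degrees of freedom remain. With an estimated correlation 9, 8, 0, 0 and 0 lists were called in the comparisons in that order, and fry called 8 for the difference and 3 for stage in the knockout; the cause was not tested. DESeq2 called 6846, 8257, 5183, 7042 and 5506 genes and limma-voom 6078, 8219, 4244, 5684 and 6134. With the replicate number as a block the counts were 6114, 7512, 3851, 6109 and 4435, and 3139 for the same direction, but deviations of libraries with the same number correlated between -0.12 and 0.08, so the numbers do not pair the libraries. Depth limits genes near 0 counts: a group with 0 counts bounds a fold change by its floor of 3 counts, and the smallest library held 23402052 counts.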

Other observations

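Notch pathway genes, which hold progenitors back from differentiation, moved both ways. Of 14 Notch pathway genes, 7 were higher and 1 lower at E41 (7 and 2 list-adjusted), with a median of 0.42 (0.28 to 0.71 over alternatives) and camera adjusted p = 0.12 (0.016 to 0.27). Notch pathway genes passed the test without KO E41 replicate 2 (0.016). At E62, 5 were higher and 7 lower (5 and 7 list-adjusted), with a median of -0.63 (-0.72 to -0.20 over alternatives) and camera adjusted p = 0.37 (0.071 to 0.57). The receptor gene NOTCH1 rose by 1.31 ± 0.18 at E41, and the ligand genes JAG2 and DLL1 changed by -2.20 ± 0.18 and -2.23 ± 0.26 at E62. Of 12 Schwann cell genes, 5 were higher and 1 lower at E41 (5 and 1 list-adjusted), with a median of 0.72 (0.47 to 1.12 over alternatives) and camera adjusted p = 0.19 (0.061 to 0.46). At E62, 2 were higher and 2 lower (1 and 2 list-adjusted), with a median of -0.06 (-0.30 to 0.25 over alternatives) and camera adjusted p = 0.64 (0.17 to 0.998). The neuregulin receptor gene ERBB3 changed by -2.64 ± 0.24 at E41 and -4.64 ± 0.27 at E62, and FOXD3, a neural crest factor, by -3.91 ± 0.37 at E62. Of 12 neuronal genes, 1 was higher and 0 lower at E41 (0 and 0 list-adjusted), with a median of 1.03 (0.56 to 1.32 over alternatives) and camera adjusted p = 0.19 (0.059 to 0.46).

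Genes of skeletal tissues differed in direction. Of 12 bone genes, 1 was higher and 1 lower at E41 (1 and 1 list-adjusted), with a median of 0.30 (0.16 to 1.43 over alternatives) and camera adjusted p = 0.77 (0.11 to 0.997). At E62, 4 were higher and 3 lower (4 and 3 list-adjusted), with a median of 1.40 and camera adjusted p = 0.37 (0.16 to 0.83). At E41 the mean and median of the bone list have opposite signs. RUNX2, the osteoblast factor, changed by 2.33 ± 0.50 at E41 and 5.04 ± 0.60 at E62, and osteocalcin BGLAP by -2.19 ± 0.42 at E62. For RUNX2 at E41, the adjusted p of 0.010 became 0.072 without WT E41 replicate 1 and 0.0505 without WT E41 replicate 2 (3.6e-06 to 0.088 over alternatives). Of 15 tendon genes, 1 was higher and 0 lower at E41 (0 and 0 list-adjusted), with a median of 0.62 (0.16 to 1.25 over alternatives) and camera adjusted p = 0.34 (0.017 to 0.999). Tendon genes passed the test without WT E41 replicate 1 (0.036) and KO E41 replicate 1 (0.017). At E62, 5 were higher and 3 lower (5 and 3 list-adjusted), with a median of 0.31 (-0.02 to 0.62 over alternatives) and camera adjusted p = 0.59 (0.39 to 0.89). At E62 the mean of the tendon list has the opposite sign. The tendon factor SCX changed by -2.23 ± 0.58 at E62. For SCX, the adjusted p of 0.015 became 0.070 without WT E62 replicate 1 and 0.057 without KO E62 replicate 2 (0.0011 to 0.070 over alternatives).

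Of 22 cartilage genes, 3 were higher and 0 lower at E41 (2 and 0 list-adjusted), with a median of 1.70 (-0.73 to 3.74 over alternatives) and camera adjusted p = 0.073 (9.2e-06 to 0.99). Cartilage genes passed the test without WT E41 replicate 1 (0.015), KO E41 replicate 1 (9.2e-06) and KO E62 replicate 1 (0.0497) and with DESeq2 and no low-count filter. Their median was 3.74 without WT E41 replicate 1, 2.77 without KO E41 replicate 1 and -0.73 without KO E41 replicate 2. At E62, 3 were higher and 1 lower (3 and 1 list-adjusted), with a median of 1.17 and camera adjusted p = 0.30 (0.10 to 0.82). Cartilage medians per library were 0.38 and 3.92 in the knockout E41 libraries and 1.45 and -0.19 in the wild-type E41 libraries. SOX6, active in cartilage and in muscle fibres, changed by -3.48 ± 0.37 at E62. Of 14 hypoxia genes, 0 were higher and 5 lower at E41 (0 and 5 list-adjusted), with a median of -0.31 (-0.44 to -0.02 over alternatives) and camera adjusted p = 0.14 (0.035 to 0.41). Hypoxia genes passed the test without WT E41 replicate 1 (0.035) and KO E62 replicate 1 (0.043) and with no low-count filter. At E62, 3 were higher and 4 lower (3 and 4 list-adjusted), with a median of -0.05 (-0.18 to 0.26 over alternatives) and camera adjusted p = 0.88 (0.38 to 0.999). The glycolytic genes PGK1 and LDHA changed by -1.14 ± 0.10 and -1.5 ± 0.25 at E41.

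Of 14 p53 targets, 1 was higher and 5 lower at E41 (1 and 5 list-adjusted), with a median of -0.14 (-0.25 to 0.15 over alternatives) and camera adjusted p = 0.30 (0.025 to 0.44). P53 targets passed the test with fry. At E62, 2 were higher and 7 lower (2 and 7 list-adjusted), with a median of -0.46 (-0.73 to -0.16 over alternatives) and camera adjusted p = 0.15 (0.0025 to 0.22). P53 targets passed the test without WT E62 replicate 2 (0.0495) and KO E62 replicate 1 (0.045) and with limma-voom, no low-count filter and fry. CDKN1A, the cell cycle inhibitor that also rises as myoblasts leave the cycle, changed by -6.19 ± 0.41 at E41 and -6.47 ± 0.41 at E62. Of 14 fibroblast growth factor genes, 4 were higher and 6 lower at E41 (6 and 6 list-adjusted), with a median of -0.05 (-0.11 to 0.24 over alternatives) and camera adjusted p = 0.58 (0.042 to 0.70). Fibroblast growth factor genes passed the test without KO E41 replicate 2 (0.042). At E62, 4 were higher and 5 lower (4 and 5 list-adjusted), with a median of -0.03 (-0.14 to 0.28 over alternatives) and camera adjusted p = 0.88 (0.25 to 0.998). The feedback inhibitor SPRY4 changed by -1.29 ± 0.11 at E41 and -1.57 ± 0.11 at E62, and the target ETV4 by -1.72 ± 0.23 and -2.40 ± 0.24.

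Of 7 melanocyte genes, 2 were higher and 0 lower at E41 (2 and 0 list-adjusted), with a median of 0.91 (0.64 to 2.86 over alternatives) and camera adjusted p = 0.27 (0.091 to 0.50). At E62, 2 were higher and 0 lower (2 and 0 list-adjusted), with a median of 2.23 (0.92 to 2.81 over alternatives) and camera adjusted p = 0.20 (0.019 to 0.37). Melanocyte genes passed the test without KO E62 replicate 2 (0.019). The pigment enzyme gene DCT changed by 2.23 ± 0.53 at E62. For DCT, the adjusted p of 0.016 became 0.086 without WT E62 replicate 1 and 0.095 without WT E62 replicate 2 (7.0e-07 to 0.10 over alternatives). Of 17 epidermal genes, 0 were higher and 0 lower at E41 (0 and 0 list-adjusted), with a median of 0.28 (-0.17 to 0.71 over alternatives) and camera adjusted p = 0.76 (0.54 to 0.98). Of 20 adipocyte genes, 5 were higher and 3 lower at E41 (6 and 3 list-adjusted), with a median of -0.09 (-0.43 to 0.21 over alternatives) and camera adjusted p = 0.86 (0.77 to 0.997). At E62, 8 were higher and 4 lower (9 and 4 list-adjusted), with a median of 0.38 (0.19 to 0.69 over alternatives) and camera adjusted p = 0.30 (0.036 to 0.51). Adipocyte genes passed the test without KO E62 replicate 1 (0.036). At E41 the mean and median of the adipocyte list are negative and the direction of its test is upward. PPARG changed by 3.37 ± 0.32 at E62. Of 18 limb position genes, 8 were higher and 2 lower at E62 (8 and 2 list-adjusted), with a median of 0.70 (fitted 0.31 to 1.26 over alternatives) and camera adjusted p = 0.072 (0.0025 to 0.15). Limb position genes passed the test without WT E41 replicate 1 (0.044), WT E62 replicate 1 (0.019) and WT E62 replicate 2 (0.018) and with limma-voom, no low-count filter, the replicate block and fry. Of 13 red blood cell genes, 1 was higher and 1 lower at E62 (1 and 0 list-adjusted), with a median of 1.06 (0.33 to 1.67 over alternatives) and camera adjusted p = 0.30 (0.022 to 0.80). Red blood cell genes passed the test without WT E62 replicate 1 (0.039) and KO E62 replicate 1 (0.022). MYF5 in wild type changed by 0.67 ± 0.24 from E41 to E62. For MYF5, the adjusted p of 0.081 became 0.011 without WT E62 replicate 2 (0.011 to 0.26 over alternatives).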
